A study of soil metagenome with 15 samples.

How the data were processed

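The series holds RNA sequencing of microbial consortia that were enriched from soil of Prosser, Washington, in liquid M9 minimal medium with different carbon sources. There were 15 libraries in 5 enrichments of 3: glucose with the aminoglycoside antibiotic gentamycin (replicates 2, 3 and 4), n-acetylglucosamine (4, 7 and 8), pectin (3, 4 and 8), xylan (11, 13 and 15) and xylose (2, 3 and 4). For xylose replicate 4 the free-text description names xylan, while its title and its enrichment label name xylose, and it was kept as xylose. Per the labels' protocols, RNA was extracted with Trizol, treated with Turbo DNase, depleted of ribosomal RNA with a MicrobExpress kit and sequenced on an Illumina HiSeq.

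Per the submitters' processing notes, HTSeq and DESeq were used. Their versions, the aligner and the assembler are not given in the sources used here. Per the file headers, genes were predicted on the assembled scaffolds with Prodigal in metagenomic mode, and the gene-call score and confidence used here are those that the authors deposited with the annotation. The authors deposited raw counts per predicted gene for each library, over 10875824 predicted genes, together with a table of raw counts for 6947 genes in all 15 libraries and a table of the same genes on a log2 scale (variance-stabilised values). Every value of the deposited count table equalled that of the per-library files. The 6947 genes all had a count in at least 12 libraries and a total of at least 75. 1844779 further genes had a count and were outside the table, and they held 2.59 to 31.4% of the gene counts of a library. The annotation carries 0 gene names or products, and the files do not pair the gene identifiers with names, so the lists of gene functions drawn up beforehand could not be tested.

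Gene counts summed to 10912912 to 20365390 per library, 7.78 to 13.2% of the records. HTSeq's classes that name no gene stayed out of library sizes and tests: 35.8 to 64.4% of records fell on no gene, 25.8 to 48.2% had a low alignment quality, 0.887 to 8.45% were not aligned and 0.0694 to 0.624% were ambiguous. Pairs of libraries of 1 enrichment differed far beyond sampling noise, with a chi-square per degree of freedom of 146 to 4460, so no library was counted as a duplicate. The labels do not say that libraries of 1 enrichment came from separate cultures, and p-values therefore measure only the spread between these samples, which may be technical. Counting intervals and floors cover counting error only.

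Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, filterByExpr with a minimum count of 10) in 1 model over all 15 libraries, and an adjusted p (Benjamini-Hochberg) below 0.05 was called. After the filter 6874 genes were tested. The SE printed beside a log2 fold change is the size of that change divided by the square root of its F statistic. It is not a standard error taken from the fit and does not give an interval. The comparisons were all 5 enrichments together, each enrichment against the unweighted mean of the other 4, polymers (pectin and xylan) against single sugars (the other 3), xylan against xylose, and glucose with gentamycin against xylose. Other scalings (median-of-ratios size factors, library totals alone), no filter, DESeq2 1.42.0, limma-voom (limma 3.58.1), a log2 fold change of at least 1, the replicate number as a block, only the libraries of the 2 groups compared, and leaving out each library in turn were among the alternatives planned in the same way.

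Whole profiles were compared by PERMANOVA on Bray-Curtis dissimilarity of CPM (counts divided by the total of the library over the genes of the series table and scaled to a common total, without TMM) over the 6947 genes with 100000 permutations. Detected genes were counted over all predicted genes after thinning each library to the smallest total (10912912, mean of 10 draws), and the inverse Simpson index gave the effective number of genes. These and the other group values were tested with a 1-way F statistic and 100000 permutations, or with all arrangements within a set of libraries (560 and 140). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

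The following definitions were chosen after seeing the data. A confident gene had a call confidence of at least 99 and lay on a scaffold of which at least 70% was coded. A little coded scaffold had less than 50% coded sequence. GC classes of 10 percentage points, with the mean GC, made 6 tests in each of 3 gene sets. A scaffold of at least 10 genes was called broadly transcribed in a library when at least 50% of its genes had at least 3 counts. These counts were taken after thinning to the smallest total, and values taken as traces, as defined below, were left out. An earlier rule for leading scaffolds, all 3 libraries of an enrichment above the other 12 in share of counts, was replaced by this one because most scaffolds it picked had 1 gene counted in all 3 libraries. The intraclass correlation of fold changes along scaffolds, and the share of scaffolds whose called genes changed one way, were also added then.

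The libraries were also sorted, after seeing the data, into set A (8 libraries) and set B (7) from traces that genes counted almost entirely in 1 library left in others. Set A holds glucose with gentamycin 2 and 3 and all n-acetylglucosamine and xylose libraries. Set B holds glucose with gentamycin 4 and all pectin and xylan libraries. In 7 pairs, a library of 1 set and its partner in the other exchanged more traces. Traces were taken as up to 1000 ppm of the counts of the other libraries of the set and 5000 ppm of those of the partner, limits set near or above the highest observed rates (1080 and 4023 ppm). Fits with the set as a term, with traces removed, with confident genes only and over all predicted genes (156811 had at least 30 counts in all, of which 45974 passed the low-count filter) were added then.

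The rule for named genes, fixed before the data were examined, ranked called genes by the size of the log2 fold change, among those with a mean of at least 10 CPM on the higher side and all libraries of the 2 sides apart. It allowed more genes than are printed: because the identifiers carry no names, the text gives the first 2 higher and the first 2 lower genes of a comparison. The rule also left genes without a known function unnamed. As the annotation gives no functions, that clause was not applied. For genes with 0 to 3 counts on the lower side, a ratio chosen after seeing the data was printed: the geometric mean, over the enrichments of the higher side, of their mean CPM scaled with TMM, over the pooled counts of the lower side scaled in the same way. Where these were 0, a floor of 3 counts over the group took their place. With 1 to 3 counts the ratio has a 95% counting interval. These ratios were also computed with library totals, with median-of-ratios size factors and without each library in turn. The edgeR test was tested on simulated data for xylan against the other enrichments, with 6874 genes and 50 genes changed at each size: 12% of genes changed 4-fold were recovered, 70% at 16-fold, 80% at 64-fold and 84% at 256-fold, and 9 of 132 calls were unchanged genes. With no simulated group effect in 6863 genes, edgeR called 0 genes in every comparison. Both simulations drew each gene independently, whereas real genes of a scaffold tended to change together. They therefore do not give the number of false calls to expect in the real data. The tests on group values were run on 40 simulated draws of each kind: with no group effect the F test gave p below 0.05 in 3 draws and PERMANOVA in 2, and with a group effect both did in all 40.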

Results

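RNA of soil consortia grown on 5 carbon sources was sequenced to compare their transcript profiles. Each enrichment had 3 libraries: glucose with the antibiotic gentamycin, n-acetylglucosamine (the monomer of chitin), pectin and xylan (plant cell wall polysaccharides) and xylose (the main sugar of xylan). Between 10912912 and 20365390 counts per library fell on predicted genes. 1851726 genes had a count, and 63.4% of them were counted in 1 library only.

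On average, libraries of 1 enrichment resembled each other more than libraries of different enrichments, though this did not hold throughout for pectin. Glucose with gentamycin and xylan were the most uniform, with mean Bray-Curtis dissimilarities of 0.215 and 0.198 among their 3 libraries. Pectin was the least uniform at 0.693, above its mean to xylan (0.657) and below its means to the other enrichments (0.734 to 0.883). N-acetylglucosamine and xylose were the closest pair of enrichments (0.578), and glucose with gentamycin and n-acetylglucosamine the most distant (0.9004). The mean was 0.390 ± 0.225 (SD, 15 pairs) within enrichments and 0.752 ± 0.135 (SD, 90 pairs) between them, and the enrichment accounted for 73.1% of the variation (multivariate permutation test on the dissimilarities, permutation p = 1e-05, the smallest the permutations can give). It accounted for 73.9% within set A (exact permutation p = 0.00357) and 57.6% within set B (exact permutation p = 0.0286). N-acetylglucosamine 4 lay nearest to xylose 4 (0.420, against 0.537 to its own enrichment) and pectin 8 nearest to glucose with gentamycin 3 (0.507 against 0.7005). Pectin 8 was nearer to every glucose with gentamycin library (0.507 to 0.549) and every xylan library (0.535 to 0.572) than to pectin 3 or 4. Over all genes pectin 3 lay nearest to xylose 3 (0.614, against 0.626 to its own enrichment). Over confident genes only, n-acetylglucosamine was the most uniform (0.352), and glucose with gentamycin and xylan had 0.591 and 0.615. Over these genes n-acetylglucosamine 4 lay nearest to its own enrichment (0.440), pectin 8 still to glucose with gentamycin (0.635), and xylose 2 to n-acetylglucosamine 8 (0.393).

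**Figure D1:**
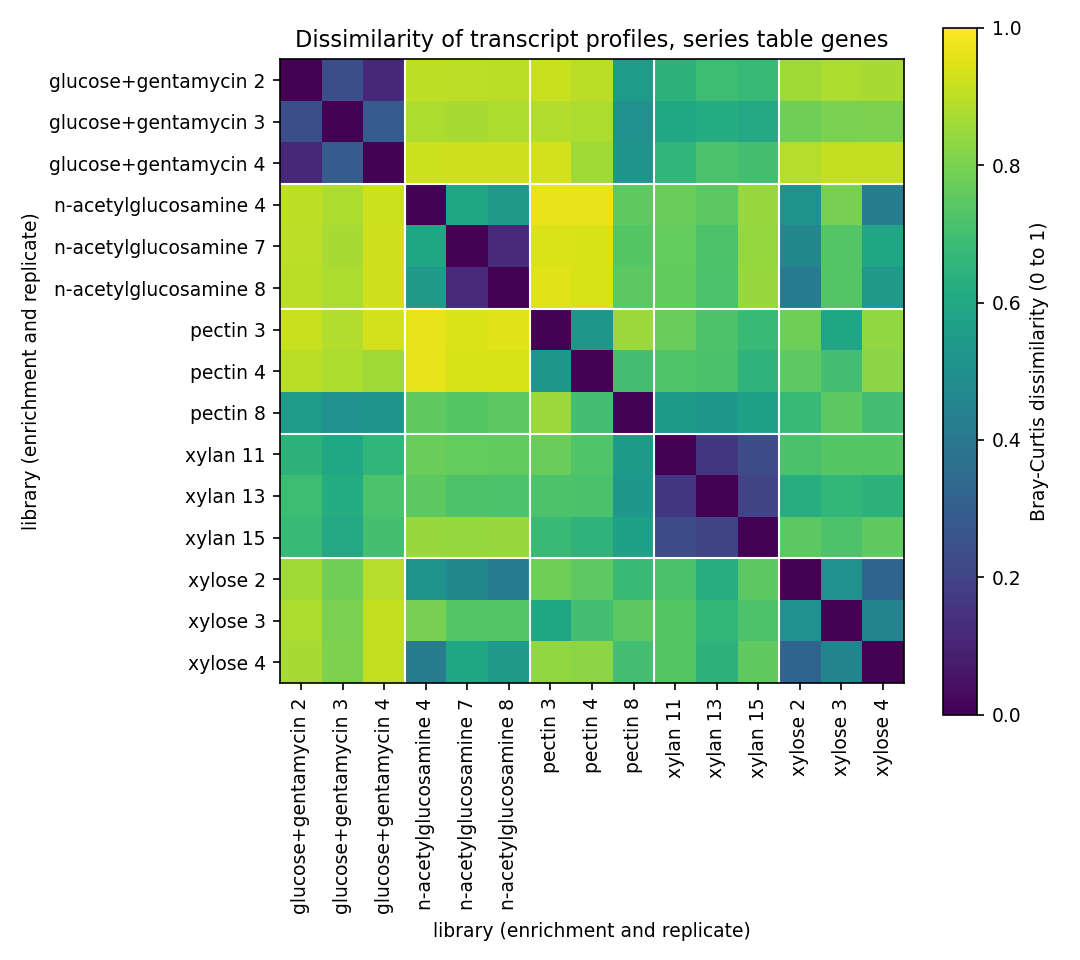
Bray-Curtis dissimilarity (colour, 0 to 1) of CPM over the genes of the series table for each pair of the 15 libraries, with white lines between enrichments. Blocks on the diagonal are darkest for xylan (mean 0.198) and glucose with gentamycin (0.215) and lightest for pectin (0.693).

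The number of genes detected at equal depth differed among the enrichments, with overlap between libraries. The mean was 305015 ± 49790 genes in xylan, 230914 ± 45878 in glucose with gentamycin, 217124 ± 70028 in pectin, 118988 ± 53221 in n-acetylglucosamine and 102583 ± 20474 in xylose (SD, n = 3 each; permutation p = 0.00426, F = 8.30). Glucose with gentamycin 3 (283493) and pectin 8 (269953) lay above xylan 13 (263424), and the lowest library was n-acetylglucosamine 4 (59253.5). Within set A the groups differed (exact permutation p = 0.025). Within set B they did not differ by more than the spread between libraries (exact permutation p = 0.343). The effective number of genes was lowest in glucose with gentamycin (7.69 ± 3.74, SD, n = 3) and 14.9 to 24.1 in the other enrichments, a difference within the spread (permutation p = 0.235). Without n-acetylglucosamine 4 the permutation p was 0.0224. Over confident genes only the permutation p was 0.210. The mean there was 196 ± 175 in glucose with gentamycin, 97.4 without its library 3, 165 ± 13 in xylan, 133 ± 82 in pectin, 94.2 ± 62.7 in xylose and 19.9 ± 11.3 in n-acetylglucosamine (SD, n = 3 each).

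A few predicted genes held a large part of the counts. The 4 genes that led at least 1 library were chosen after their values were seen. 1 gene led all 3 libraries in glucose with gentamycin, and in the other 4 enrichments the leading gene differed between libraries. Gene 640555_1 (Scaffold464412, 202 to 777) took 34.2 ± 6.8% of the gene counts of glucose with gentamycin, 15.96 ± 1.3% in xylan and 0.334 ± 0.247% in xylose (SD, n = 3 each). Gene 1475907_2 (Scaffold3945207, 542 to 712) took 17.3 ± 19.2% in n-acetylglucosamine and 12.3 ± 9.6% in xylose. Gene 224663_3 (Scaffold5752773, 1482 to 2090) took 15.4 ± 2.0% in xylan and 11.3 ± 8.6% in pectin. Gene 1682366_2 (Scaffold293408, 1513 to 2034) took 10.9 ± 3.6% in n-acetylglucosamine and 0.0232 ± 0.0071% in glucose with gentamycin. The first 3 of these lay on scaffolds of which 14.01 to 29.5% was coded. Of the 50 most counted genes, 34 lay on little coded scaffolds. The 50 most counted genes on such scaffolds all had a call confidence below 99, so whether they are real genes is uncertain.

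The number of broadly transcribed scaffolds also differed among the enrichments, though n-acetylglucosamine and xylose overlapped. Xylan libraries had 309 to 322 broadly transcribed scaffolds, n-acetylglucosamine 180 to 203, xylose 170 to 189 and glucose with gentamycin 82.3 ± 30.4 (SD), while pectin 3 and 4 had 5 and 7 and the pectin mean was 91.3 ± 147.8 because of pectin 8 (permutation p = 0.0131, F = 5.78, n = 3 each). The exact permutation p was 0.0214 within set A and 0.1 within set B. N-acetylglucosamine, xylose and xylan shared 158 scaffolds that were broadly transcribed in all of their libraries, together 2.141 Mbp with 2276 predicted genes and a median GC content of 62.0%. Of the 173 scaffolds broad in every n-acetylglucosamine library and the 163 broad in every xylose library, 161 were the same. These 158 scaffolds held 16.9 ± 2.7% of the counts on confident genes in n-acetylglucosamine, 15.7 ± 0.5% in xylose, 5.25 ± 2.598% in xylan, 0.929 ± 1.268% in pectin and 0.149 ± 0.022% in glucose with gentamycin (SD, n = 3 each). They were picked for being broad in n-acetylglucosamine, xylose and xylan, so lower shares in pectin and glucose with gentamycin are partly built in. Shares of confident counts keep values taken as traces, which the broad scaffold counts leave out. None of the 44 scaffolds that were broad in every glucose with gentamycin library was among those of n-acetylglucosamine or xylose (0 and 0 shared), which lists this short would also give by chance. But 6 of the 44 were among the 251 broad in every xylan library, against 0.0672 if the lists were independent. The median GC content of the 44 scaffolds was 67.9%. In Scaffold27451396, chosen after its values were seen, 28 of 29 genes had at least 3 counts in every n-acetylglucosamine library. It held 0.712 ± 0.063% of confident counts there, 0.469 ± 0.080% in xylose and 0.00322 ± 0.00156% in glucose with gentamycin.

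**Figure D2:**
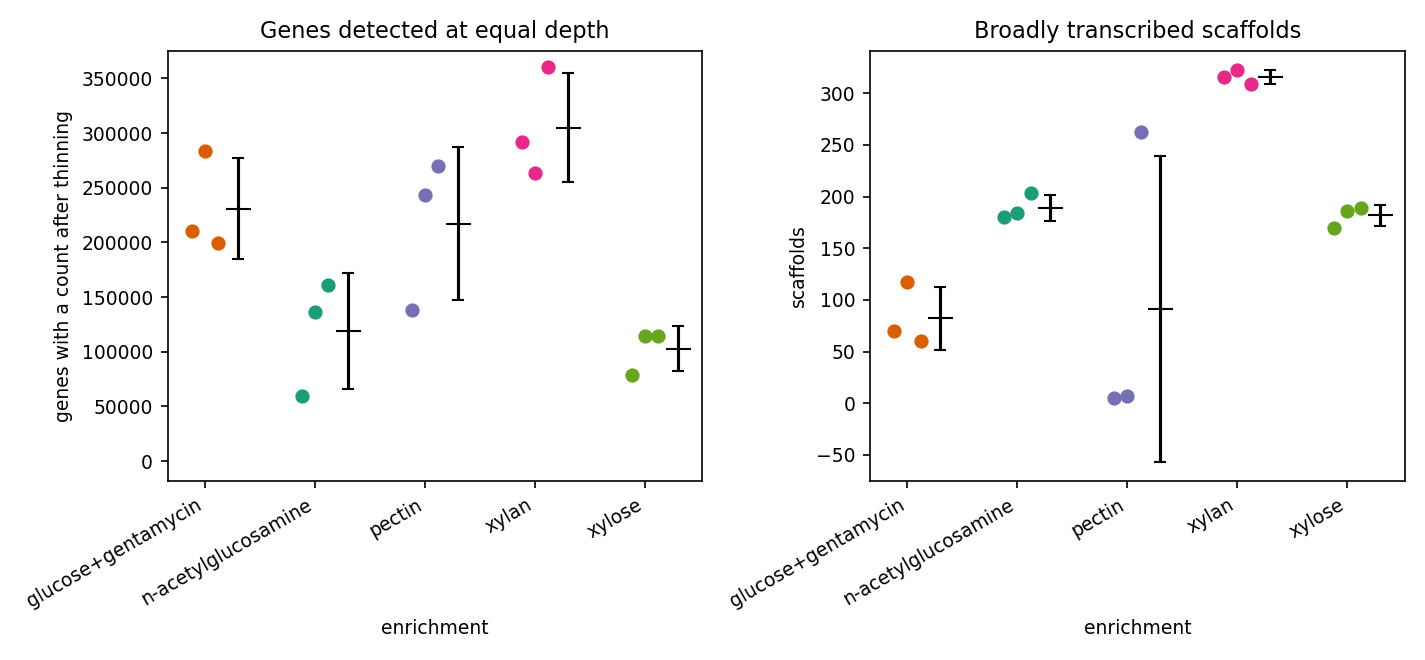
Genes with a count after thinning to equal depth (left) and broadly transcribed scaffolds (right) in each library (points), with mean and SD of the 3 libraries (bars; the lower SD bar of pectin scaffolds reaches below 0). The xylan libraries lie between 309 and 322 scaffolds, and pectin 8 lies far above the other pectin libraries, which have 5 and 7. Values taken as traces were left out of the scaffold counts.

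The share of counts on confident genes differed between enrichments in all 5 classes of GC content (adjusted permutation p = 0.00042 to 0.0295). The 60 to 70% class lost this without any 1 of 7 libraries (permutation p = 0.0508 to 0.0917). Genes of 50 to 60% GC held 54.0 ± 5.0% of confident counts in n-acetylglucosamine and 44.8 ± 5.2% in xylose, against 24.2 ± 6.5% in xylan, 21.2 ± 4.3% in pectin and 11.3 ± 3.5% in glucose with gentamycin (SD, n = 3 each; permutation p = 7e-05, adjusted p = 0.00042 over 6 tests). Genes of 40 to 50% GC held 27.8 ± 10.2% in pectin and 23.3 ± 6.7% in glucose with gentamycin, but 1.503 ± 0.316% in n-acetylglucosamine (adjusted permutation p = 0.00336, n = 3 each). The exact permutation p of both classes was 0.00357 within set A, and within set B it was 0.214 and 0.0857. Over all genes, little coded scaffolds included, glucose with gentamycin held the highest share of the 50 to 60% class (61.7 ± 5.0%, against 47.5 ± 5.4% in n-acetylglucosamine), and the classes below 40%, of 40 to 50% and of 60 to 70% did not pass the test (adjusted permutation p = 0.0600, 0.121 and 0.111, n = 3 each).

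**Figure D3:**
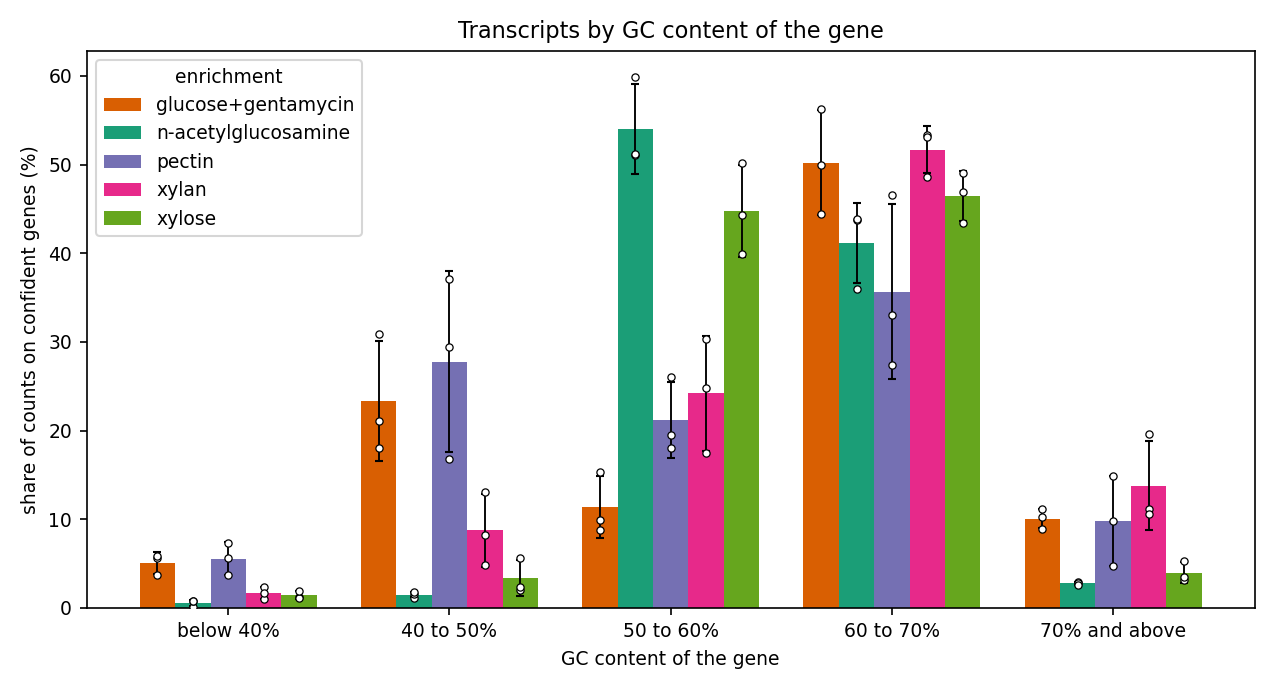
Share of counts on confident genes (vertical axis, %) by GC content of the gene (horizontal axis), as mean (bars), SD (error bars) and single libraries (points) of the 3 libraries per enrichment. The 50 to 60% class holds 54.0% in n-acetylglucosamine and 11.3% in glucose with gentamycin.

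Among the 5 enrichments edgeR called 5192 of 6874 genes with TMM, 6437 with library totals and 3123 with median-of-ratios size factors. How many rose or fell depended on the scaling. The median log2 fold change of all genes, with TMM, median-of-ratios size factors and library totals in turn, was -2.19, 0.02 and -5.06 for glucose with gentamycin, 0.64, -0.04 and 3.52 for n-acetylglucosamine, 0.41, 0.18 and -0.72 for pectin, 0.77, 0.31 and 0.86 for xylan and 0.44, -0.38 and 1.43 for xylose. It was 0.92, 0.46 and 0.15 for polymers against single sugars, 0.26, 0.58 and -0.47 for xylan against xylose and -2.20, 0.23 and -5.33 for glucose with gentamycin against xylose. Fold changes and calls below are as fitted with TMM, without these medians subtracted, and the distance from the median is given for the first gene that rose where its fold is printed. A fitted fold change sets a group against the average log2 level of the other enrichments, whereas CPM are on library totals and averaged over libraries, so the 2 do not give the same ratio. Of the values above 0 in the series table, 58.9 and 58.3% in pectin 3 and 4, 34.6 to 40.4% in glucose with gentamycin and at most 13.5% in other libraries were taken as traces. Fold changes and CPM below keep these values unless stated. Traces had a median of 508 ppm of the donor's counts in other enrichments of the same set and 2907 ppm in a partner. The low levels printed beside a gene that rose may therefore hold traces. The size of such a rise does not separate the gene's change from the trace rate. With the set as a term in edgeR, pectin, xylose and polymers had 0 calls (1634, 2164 and 1228 at an unadjusted p below 0.05) and xylan and xylan against xylose 1 each. All pectin and xylan libraries are in set B and all n-acetylglucosamine and xylose libraries in set A, so for these the set and the carbon source cannot be told apart beyond what the glucose with gentamycin libraries bridge.

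**Figure D4:**
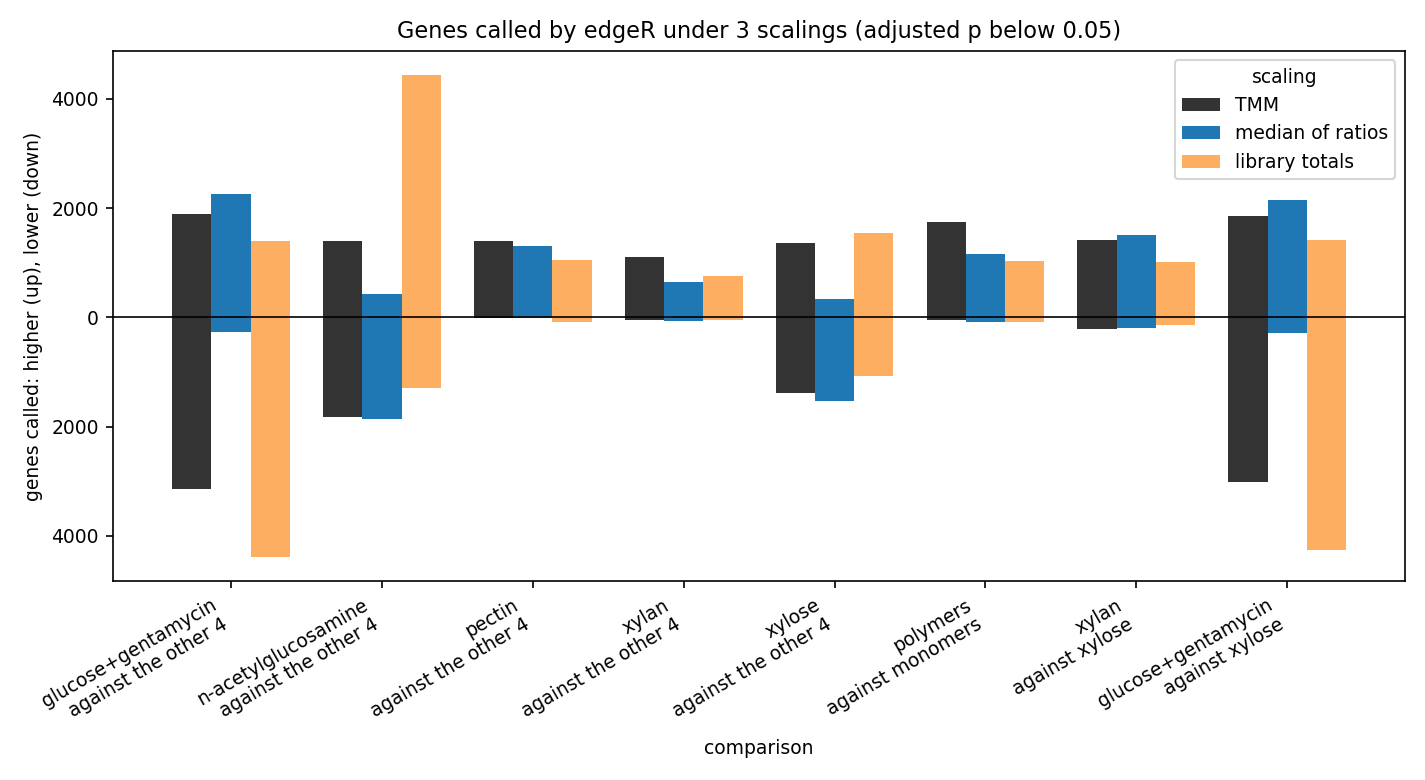
Genes called higher (bars up) and lower (bars down) by edgeR in each comparison (horizontal axis) under 3 scalings (colours). For glucose with gentamycin the lower calls number 3149 with TMM and 264 with median-of-ratios size factors.

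With each of the 3 scalings in edgeR, glucose with gentamycin had the most calls of the 5 enrichments, but DESeq2 called more for n-acetylglucosamine (2627) and xylose (2612) than for it (2357). Of the genes of the series table, 1886 were higher and 3149 lower. Gene 582015_35 (Scaffold28365848, 27098 to 34669, minus strand) rose by 12.50 on the log2 scale (SE 1.251, adjusted p = 2.17e-06, edgeR), 14.69 above the median of all genes, and by 10.20 with library totals. It had 313 ± 484 CPM, against 0.439 ± 0.400 in the other libraries (SD, n = 3 and 12). Gene 1342490_1 (Scaffold9236059, 2 to 1258, minus strand) rose by 11.91 (SE 1.271). Gene 1569963_5 (Scaffold18019894, 3920 to 4699, minus strand) had 0 counts against 35.5 ± 50.7 CPM elsewhere (SD, n = 12; edgeR adjusted p = 0.000433). It was at least 25.04-fold lower with TMM, 12.7-fold without glucose with gentamycin 4, and at least 5.01-fold with median-of-ratios size factors. Gene 247144_9 (Scaffold23791755, 8536 to 8982, minus strand) also had 0 counts (adjusted p = 0.0206) and was at least 15.8-fold lower with TMM, 7.98-fold without glucose with gentamycin 4, 8.86-fold without n-acetylglucosamine 4 and 3.29-fold with median-of-ratios size factors. The call of 247144_9 was lost without glucose with gentamycin 2, 3 or 4 (adjusted p = 0.0502, 0.0616 and 0.0767; 0.000614 to 0.285 over all alternatives). Of all 6874 genes tested, 5.24% had higher and 21.2% lower CPM in each of the 3 libraries than in any of the other 12, which chance gives for 0.22% of genes in each direction. Median-of-ratios size factors gave 2265 higher and 264 lower genes, library totals 1395 and 4389 and DESeq2 2076 and 281, and 1395 and 264 genes kept their sign and call under the 3 scalings in edgeR. Over 45974 genes from all predicted genes, edgeR with TMM called 27778 higher and 6733 lower, the opposite balance to the series table.

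In n-acetylglucosamine 1394 genes were higher and 1825 lower. Gene 1437375_3 (Scaffold6189473, 1414 to 2433, minus strand) rose by 6.20 on the log2 scale (SE 1.02, adjusted p = 0.00431, edgeR), 5.56 above the median of all genes, and by 7.96 with library totals. It had 115 ± 122 CPM, against 0.556 ± 0.644 elsewhere (SD, n = 3 and 12). Gene 825987_1 (Scaffold22846594, 184 to 504, minus strand) rose by 5.44 (SE 1.154), a call lost without n-acetylglucosamine 4 (adjusted p = 0.0868; 7.74e-07 to 0.99999 over all alternatives). Gene 1413041_1 (Scaffold32141512, 2 to 889, minus strand) had 1 count in the 3 libraries and was 5274-fold lower than in the other enrichments with TMM (counting interval 947 to 208331; edgeR adjusted p = 0.00431). The ratio was 3221 without n-acetylglucosamine 7, 794 without n-acetylglucosamine 8 and 550 with library totals, and xylose was itself low at 0.215 CPM. Gene 486729_2 (Scaffold2347217, 289 to 1929, plus strand) had 0 counts and was at least 769-fold lower with TMM (470, 347 and 510 without n-acetylglucosamine 7, n-acetylglucosamine 8 and pectin 4) and 74.97-fold with library totals. In CPM, 7.80% of the tested genes lay above and 0.931% below all other libraries (0.22% by chance). Median-of-ratios size factors gave 420 higher and 1867 lower genes, library totals 4437 and 1289 and DESeq2 2627 in all, 650 of them higher, and 420 and 1245 genes were called under the 3 scalings. With the set as a term 16 genes were higher and 1346 lower, and 1437375_3 was not called (adjusted p = 0.164; 3.38e-09 to 0.164 over all alternatives).

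In pectin most called genes were higher, 1389 against 10 lower. None of these calls remained with the set as a term, so set and carbon source cannot be told apart here. Gene 269445_3 (Scaffold31803729, 987 to 1619, plus strand) rose by 13.88 on the log2 scale (SE 1.7197, adjusted p = 2.13e-05, edgeR), 13.47 above the median of all genes, and by 9.72 with library totals. It had 986 ± 1366 CPM, against 1.36 ± 1.88 elsewhere (SD, n = 3 and 12). Gene 1815863_5 (Scaffold474810, 1971 to 2822, minus strand) rose by 13.78 (SE 1.85). Gene 1481689_4 (Scaffold1012522, 3431 to 3559, plus strand), which is not a confident gene, had 2 counts in the pectin libraries and was 110.5-fold lower than in the other enrichments with TMM (counting interval 30.6 to 912; edgeR adjusted p = 0.0113), and 8.91-fold without pectin 8. Its level elsewhere came mostly from xylose (1569 CPM, against 2.66 to 4.90 in the others). Gene 541660_4 (Scaffold1675956, 2043 to 2414, plus strand), also not a confident gene, fell by 5.67 (SE 1.78, adjusted p = 0.0297). The call of 1481689_4 was lost without pectin 8 (adjusted p = 0.0593) and with traces removed (0.925; 1.01e-05 to 0.966 over all alternatives), and that of 541660_4 without pectin 3 or 8 (0.0978 and 0.110; 0.000313 to 0.319). In CPM, 0.975% of the tested genes lay above and 0.320% below all other libraries (0.22% by chance), and 939 higher and 8 lower genes were called under the 3 scalings.

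In xylan, too, far more genes were higher than lower, 1108 against 51. Almost none of these calls remained with the set as a term, so set and carbon source cannot be told apart here. Gene 1352166_14 (Scaffold405169, 12734 to 14107, minus strand) rose by 10.10 on the log2 scale (SE 1.47, adjusted p = 0.000399, edgeR), 9.33 above the median of all genes, and by 11.08 with library totals. It had 8337 ± 7307 CPM, against 11.8 ± 13.5 elsewhere (SD, n = 3 and 12). Gene 1800942_10 (Scaffold11042358, 7597 to 8478, minus strand) rose by 10.10 (SE 1.584). Gene 1129114_4 (Scaffold17639160, 3466 to 4092, minus strand) fell by 9.13 (SE 2.75, adjusted p = 0.0319, edgeR), and gene 582015_35 had 1 count and was 177-fold lower than in the other enrichments with TMM (counting interval 31.7 to 6986; adjusted p = 0.0219), 37.8-fold without xylan 11 and 89.5-fold without xylan 13. Its level elsewhere came mostly from glucose with gentamycin (313 CPM, against 0.340, 0.383 and 1.008 in n-acetylglucosamine, pectin and xylose). Both lower calls were lost without any 1 of xylan 11, 13 and 15 (adjusted p = 0.133, 0.102 and 0.108 for 1129114_4, and 0.0585, 0.0844 and 0.0992 for 582015_35). In CPM, 1.673% of the tested genes lay above all other libraries and 0.102% below, the latter under the 0.22% that chance gives. Without xylan 15 edgeR called 552 genes and without xylan 11 733. DESeq2 called 748 higher and 370 lower genes, and 510 higher and 19 lower genes were called under the 3 scalings.

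In xylose 1354 genes were higher and 1379 lower. None of these calls remained with the set as a term, so set and carbon source cannot be told apart here. Gene 1635164_2 (Scaffold27441274, 506 to 1555, plus strand) rose by 9.14 on the log2 scale (SE 0.89, adjusted p = 0.00013, edgeR), 8.70 above the median of all genes, and by 10.38 with library totals. It had 2008 ± 619 CPM, against 2.47 ± 2.07 elsewhere (SD, n = 3 and 12). Gene 1481689_4, low in pectin, rose by 9.12 (SE 1.05). Gene 42959_1 (Scaffold606589, 2 to 610, plus strand) had 0 counts in xylose (edgeR adjusted p = 0.0167). Its mean was 256.5 CPM in pectin, 3.21 in glucose with gentamycin, 2.42 in n-acetylglucosamine and 0.205 in xylan, and it was at least 320-fold lower in xylose with TMM, 66.3-fold with library totals, and 149.5 and 199-fold with TMM without n-acetylglucosamine 4 and xylose 2. Gene 190365_8 (Scaffold14829205, 9067 to 11592, minus strand) was at least 309-fold lower with TMM (adjusted p = 0.00776; 198.9 and 193 without pectin 4 and xylose 2) and 116-fold with library totals. The call of 42959_1 was lost without xylose 2 (adjusted p = 0.0565) or 3 (0.0526) and with traces removed (1; 4.73e-08 to 1 over all alternatives). In CPM, 0.727% of the tested genes lay above and 0.436% below all other libraries (0.22% by chance). Median-of-ratios size factors gave 339 higher and 1538 lower genes and DESeq2 596 and 2016, and 339 and 1042 were called under the 3 scalings. Without xylose 2, 3 or 4 in turn the calls fell to 1243, 1392 and 1635.

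In polymers, pectin and xylan together, 1749 genes were higher and 45 lower than in the 3 single sugars. Gene 1136114_1 (Scaffold29517622, 869 to 2056, plus strand) rose by 9.46 on the log2 scale (SE 1.4501, adjusted p = 0.000407, edgeR), 8.55 above the median of all genes, and by 6.82 with library totals. It had 130 ± 158 CPM in pectin and 8.17 ± 5.65 in xylan, against 0.344 ± 0.442 elsewhere (SD, n = 3, 3 and 9), and the fold was 7.24 without pectin 3. Gene 1511035_2 (Scaffold4568108, 414 to 719, minus strand) rose by 7.10 (SE 1.09). Neither is a confident gene. They were among 6 of all tested genes (0.0873%) whose 6 polymer libraries all lay above the other 9, and 1 gene (0.0145%) lay below, where chance gives 0.02% each way. DESeq2 called 1359 higher and 209 lower genes, and 905 higher and 41 lower genes were called under the 3 scalings. With the set as a term both named calls were lost (adjusted p = 0.272; 2.44e-12 to 0.272 over all alternatives of 1136114_1).

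Xylan, a polymer, was also set against xylose, its main sugar. edgeR called 1637 genes, of which 218 were lower on xylan and the others higher. Almost none of these calls remained with the set as a term. Gene 1496115_6 (Scaffold1307561, 4011 to 4181, plus strand) averaged 665 ± 1146 CPM on xylan and had 3 counts on xylose (edgeR adjusted p = 0.0179, SD, n = 3 each). The ratio was 34019 with TMM (counting interval 11641 to 164960) and 9814 with library totals, but 67.4 with TMM without xylan 15, and 63552 without xylose 2. Gene 1800942_10 had 3 counts on xylose, a ratio of 15993 with TMM (5473 to 77552), 4758 with library totals, and with TMM 469 without xylan 15 and 29877 without xylose 2. Gene 1129114_4 fell by 9.88 on the log2 scale (SE 2.91, adjusted p = 0.0226, edgeR), and gene 1217674_1 (Scaffold1223179, 2 to 2848, minus strand) had 2 counts on xylan, a ratio of 1210.4 with TMM (335 to 9994), and 613, 2065 and 35.7 without xylan 13, xylan 15 and xylose 2. All 4 calls depended on single libraries. That of 1496115_6 was lost without xylan 15 or xylose 2, 3 or 4 (adjusted p = 0.104, 0.0600, 0.0703 and 0.0665), and that of 1800942_10 without xylose 3 or 4 (0.0578 and 0.0546). That of 1129114_4 was lost without xylan 11, 13 or 15 or xylose 2 or 3 (adjusted p = 0.0803, 0.0696, 0.0699, 0.278 and 0.0502), and that of 1217674_1 without xylose 2 (0.0707). In CPM, 23.4% of the tested genes were higher and 22.1% lower in all 3 libraries than in the other 3, which chance gives for 5% of genes in each direction, and 990 higher and 88 lower genes were called under the 3 scalings. Calls fell to 968 without xylan 15 and to 658, 290 and 397 without xylose 2, 3 and 4.

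Glucose with gentamycin and xylose differed in sugar and in antibiotic at once. 1857 genes were higher with glucose and gentamycin and 3009 lower. Gene 454746_2 (Scaffold28757943, 1346 to 1759, plus strand) averaged 110.4 ± 27.8 CPM against 1 count on xylose (edgeR adjusted p = 0.000719, SD, n = 3 each). The ratio was 48879 with TMM (counting interval 8773 to 1930620), 4886 with library totals (877 to 192997) and 262982 with median-of-ratios size factors. With TMM it was 31101 without glucose with gentamycin 2 and 10146 without xylose 2. Gene 997801_5 (Scaffold17064558, 1396 to 1929, plus strand) had 2 counts on xylose. Its ratio was 34576 with TMM (9572 to 285502), 3572 with library totals and 187773 with median-of-ratios size factors. Gene 391218_14 (Scaffold150918, 12158 to 12547, minus strand) had 0 counts with gentamycin (edgeR adjusted p = 0.00996) and was at least 63.0-fold lower than on xylose with TMM, 31.9-fold without glucose with gentamycin 4 and 11.5-fold with median-of-ratios size factors. Without xylose 3 the level on xylose was at the floor (0.974 times it) and the call was lost (adjusted p = 0.149; 0.000923 to 0.291 over all alternatives). Gene 1285533_5 (Scaffold2042982, 4033 to 4524, minus strand) was at least 34.7-fold lower with TMM (17.6 and 12.05 without glucose with gentamycin 4 and xylose 3) and 6.17-fold with median-of-ratios size factors. In CPM, 19.1% of the tested genes were higher and 60.01% lower in all 3 libraries than in the other 3 (5% by chance each way). Median-of-ratios size factors gave 2143 higher and 282 lower genes, library totals 1408 and 4263 and DESeq2 2110 and 376, and 1407 and 282 genes were called under the 3 scalings. Within set A, with 5 libraries, 1523 genes were higher and 609 lower.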

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

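Every test in this part but 3 was chosen after the result was seen: the evenness of traces, the median without little coded scaffolds and the scaffold length of little coded genes were set before their results. Several signals lay in data that the comparisons of the 6947 genes leave out. Outside the series table, 3032 genes had at least 1000 counts. The highest total was 51671, in gene 1528525_7 (Scaffold18445512, 5928 to 7460), of which 96.2% came from pectin 8. Genes outside the table took up to 31.4% of the gene counts of a library (pectin 8). Records on no predicted gene made up to 64.4% of a library (n-acetylglucosamine 4).

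Genes counted almost entirely in 1 library left small counts in others, with a median of 508 ppm of the donor's counts in libraries of other enrichments in the same set, at least 100 ppm in 66 of 72 pairs, against 0 and 6 of 94 pairs in the other set, partners aside. Partners in the other set received a median of 2907 ppm, at least 100 ppm in 14 of 14 pairs. Rare members shared alike by the libraries of an enrichment are argued against, since both directions agreed (at least 100 ppm, or less) in 78 of 90 pairs of libraries of different enrichments, against at most 72 in 1000 shuffles of recipients within their enrichment (permutation p = 0.017 without glucose with gentamycin 4), while members that differ from library to library stay open. Index exchange within a sequencing set may be the source. Trace counts there mostly followed donor counts gene by gene, with a median chi-square per degree of freedom of 1.49975 (0.535 to 148, 50 pairs). The median was 38.6 in the other set, partners aside (31 pairs), but 1.69 in partners, which also lie in the other set. Pairs with few trace counts were left out, and the sets were drawn from these same traces. Removing the traces set 58.9 and 58.3% of the values above 0 in pectin 3 and 4, 34.6 to 40.4% in glucose with gentamycin and 1.28 to 1.569% in xylan to 0, and left 2707 of the 6947 genes with a count in at least 12 libraries.

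The direction of the glucose with gentamycin changes turned with the scaling. Sequencing depth is argued against, since table totals differed by a ratio of 2.25 and size factors by 493. A few genes taking most of the counts are argued against too: with library totals and without little coded scaffolds the median log2 fold change was still -4.33. The choice of genes in the series table may account for it, since the median with library totals was -5.06 in the table and 2.99 over all genes. Over all genes 25137 were called higher and 118 lower under all 3 scalings. The low-count filter lets genes into that set through the libraries of a single enrichment. Its median thus depends on a choice of genes too, and does not settle the question. A change in which populations were active stays open as well, since the design names the antibiotic and the sugar.

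Scaffolds with little coding sequence took 22.2 to 76.3% of the gene counts of a library. Introns on such scaffolds are argued against, since 0 of the 50 most counted genes there lay on scaffolds of at least 10000 bp, where 1001 of 10020 genes with a count on little coded scaffolds did. This is a weak test, because that share of 9.99% is near the bound of 5 of 50 set beforehand, and fragmented scaffolds of such organisms were not tested. Ribosomal RNA left after depletion cannot be told apart from other sources: the GC standard deviation of these 50 genes was 0.868 times that of the 50 most counted confident genes, between the values set for either outcome. The design names no biological explanation of this pattern, and none other than these was tested.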

How the results depend on the processing

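Alternatives with the set as a term, with traces removed, with confident genes, without little coded scaffolds, over all genes or within set A, and the scaffold and GC tests, were chosen after seeing the data. The cause of a change was not tested unless stated. Of 870 recomputed fold changes for 30 named gene results, 786 kept sign and call, 84 kept the sign and lost the call (20 of 30 with the set as a term, 28 of 450 with 1 library left out) and 0 changed sign. Of 192 recomputed ratios and bounds for 15 genes with at most 3 counts on the lower side, also chosen after seeing the data, 38 left their counting interval or, for bounds, moved by 1.5 times. Requiring a log2 fold change of at least 1 moved nothing, since every called gene exceeded it, and says nothing about stability. The share of variation between enrichments stayed at 0.623 to 0.820 with permutation p below 0.05, and the permutation p of detected genes stayed below 0.05, in all alternatives run over both sets. Within set B the share of variation had an exact permutation p of 0.114 with Euclidean distance on log2 CPM. Of the tests on lists of gene functions none was run, for lack of gene names. Genes changed 4-fold were mostly out of reach (12% recovered in simulation for xylan).

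Median-of-ratios size factors gave 2529 genes for glucose with gentamycin, 715 for xylan, 2425 for glucose with gentamycin against xylose and 3123 among the 5 enrichments. Library totals gave 5726 for n-acetylglucosamine and 1117 for polymers, and without little coded scaffolds 5232 and 1013. DESeq2 gave 2357 for glucose with gentamycin and 2486 for its contrast with xylose. Limma-voom gave 818 for pectin. With the set as a term edgeR gave 1362 for n-acetylglucosamine, 1 for xylan, 1 for xylan against xylose and 0 for pectin, xylose and polymers (1634, 2164 and 1228 at an unadjusted p below 0.05). Within set A glucose with gentamycin against xylose gave 2132. With traces removed xylan gave 1965, and with confident genes 738. With traces removed and library totals n-acetylglucosamine gave 5001, xylan 699, xylose 1448, polymers 951 and xylan against xylose 637.

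Over all genes more genes were tested (45974). In the order TMM, library totals, median of ratios, the calls were 34511, 32112 and 32098 for glucose with gentamycin, 14168, 10892 and 8629 for n-acetylglucosamine, 14808, 19740 and 21429 for pectin, 21494, 12430 and 11078 for xylan, 16695, 15451 and 19516 for polymers, 21513, 10644 and 22429 for xylan against xylose, 34435, 32626 and 32054 for glucose with gentamycin against xylose and 43749, 42971 and 37830 among the 5 enrichments. Xylose gave 4461 with median-of-ratios size factors.

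The replicate numbers that glucose with gentamycin and xylose share did not pair the libraries: deviations of same-numbered libraries correlated at -0.07, 0.08 and -0.23. With a replicate block on these 6 libraries edgeR called 2098 genes, against 3911 without it, and limma-voom with the replicate number as a random block gave 830 for pectin.

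Leaving out each library in turn gave 552 to 1402 genes for xylan (552 without xylan 15, 733 without xylan 11), 1243 to 3462 for xylose (1243, 1392 and 1635 without xylose 2, 3 and 4) and 290 to 1769 for xylan against xylose (968 without xylan 15; 658, 290 and 397 without xylose 2, 3 and 4). F of the effective number of genes ranged from 1.07 to 5.2996, the highest without n-acetylglucosamine 4 (permutation p = 0.0224). Over confident genes its permutation p stayed above 0.05 with any 1 library left out. F of the 60 to 70% GC class ranged from 2.64 to 10.1, with permutation p = 0.0508 to 0.0917 without glucose with gentamycin 3, n-acetylglucosamine 4, pectin 4 or 8, xylan 13 or 15, or xylose 3. F of the mean GC ranged from 2.50 to 15.8, with permutation p = 0.0666 to 0.0892 without pectin 4 or 8 or xylan 13 or 15. F of broad scaffolds ranged from 4.04 to 130, the highest without pectin 8. Over all genes F fell to 4.08 for the class below 40% GC (permutation p = 0.0300, adjusted p = 0.0600), 2.1899 for the 40 to 50% class, 2.81 for 60 to 70% and 2.69 for the mean GC. Named genes that lost their call without 1 library are given with their adjusted p beside their values.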

Other observations

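All tests in this part were chosen after the result was seen. Pectin 8 differed from the other pectin libraries along whole scaffolds. Pectin 3 and 4 had 5 and 7 broadly transcribed scaffolds, with values taken as traces left out. In the series table these were 58.9 and 58.3% of the values above 0 in pectin 3 and 4, against 2.69% in pectin 8. Of the 158 scaffolds that were broad in all n-acetylglucosamine, xylose and xylan libraries, 157 were broad in pectin 8 and 0 in either of the others, and they held 2.39% of its confident counts against 0.219 and 0.175%, traces kept. Pectin 8 also shared 33 of the 44 scaffolds that were broad in every glucose with gentamycin library, against 1 and 1.

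Genes of 1 scaffold tended to change together. The intraclass correlation of log2 fold changes, over 7592 genes on 989 scaffolds, was 0.891 for glucose with gentamycin, 0.833 for n-acetylglucosamine, 0.765 for xylose, 0.601 for pectin and 0.503 for xylan, against at most 0.0151 in 20 shuffles of genes over scaffolds. Of 753 scaffolds with at least 5 called genes in glucose with gentamycin, 98.8% changed all one way. So did 97.7% of 434 in n-acetylglucosamine and 84.4% of 32 in pectin. In 1000 shuffles of the directions over these genes the shares were at most 8.499, 57.8 and 59.4%. In xylan 279 of 280 such scaffolds changed all one way, in xylose 16 of 16 and in polymers 36 of 37. The shuffles gave the same numbers there, since nearly all called genes were higher (2036 of 2037, 93 of 93 and 281 of 282). For xylan, xylose and polymers this share therefore cannot show whether genes of a scaffold changed together. The hypothesis that the active populations differ between enrichments predicts intraclass correlations above the shuffles, and all 5 were above them. These shuffles break up scaffolds and do not regroup the libraries. They therefore show that genes of a scaffold changed together, and cannot tell whether the enrichments are the reason. Nor do the values separate such a difference from changes that a population makes along its whole genome, and the libraries hold no measure of cell numbers.

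Other splits of the same libraries were drawn to ask whether chance can be excluded. In 100 splits the real one alone (1 of 100) gave as many genes for all 5 enrichments (5192, highest other 1891). The same held for glucose with gentamycin (5035 and 1425), n-acetylglucosamine (3219 and 1299), xylose (2733 and 2041) and polymers (1794 and 775). For pectin (1399, highest other 1416) and xylan (1159, highest other 1253) 2 of 100 gave as many, the real split and 1 other that exceeded it, a share under 0.05. The other splits break up the enrichments, so that real differences add to the spread within their groups, and they called a median of 0 genes. A low share thus speaks against all libraries being alike, but does not exclude chance for a single comparison. For polymers, splits that regroup whole enrichments were not drawn. The splits ignore the sets and do not exclude an effect of the sets. With the set as a term edgeR called 5119 genes for all 5 enrichments, 5071 for glucose with gentamycin and 1362 for n-acetylglucosamine, while pectin, xylose and polymers had 0 calls (1634, 2164 and 1228 at an unadjusted p below 0.05) and xylan 1. The splits that exceeded pectin and xylan grouped glucose with gentamycin 2 and 4 with xylan 15, and glucose with gentamycin 3 and 4 with pectin 8, and neither followed the sets. For xylan against xylose (1637, highest other 0) and glucose with gentamycin against xylose (4866, highest other 46) the 10 splits are too few for a share under 0.05, the real split being 1 of them.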
